A study of Mus musculus with 2 samples.

How the data were processed

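Intestine of mouse embryos at day 14.5 was assayed by H3K9me3 chromatin immunoprecipitation and sequencing in 2 biological replicates, each with 2 technical replicates, per the labels. The pools held both sexes, 24 embryos in replicate 1 and 34 in replicate 2, with a library size range of 300 to 500 bp. Both replicates form 1 group, so nothing was tested between conditions.

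The authors deposited 4 peak lists in narrowPeak form on mm10, namely 1 per replicate, 1 called on both replicates together (pooled) and 1 of pooled peaks kept as replicated. The deposited descriptions record that the replicate 1 list was derived from its alignments and 2 further files, the replicate 2 list from its alignments and 1 of these files, and the pooled list from all of them. The further files were taken here to be the controls, which the descriptions do not say outright. They also record that the replicated list was derived from the pooled list and both replicate lists. The deposited fold enrichment of each peak, the signal value of the narrowPeak format, was read as a ratio of ChIP to control made by the authors. The deposited −log10 p and −log10 q values of each peak were likewise made by the authors. The aligner, the peak caller, its version and its threshold are not given in the sources used here, and read depth is unknown. Fold and −log10 values were used only to describe, rank or filter peaks within a list. Replicate lists that differ in length by this much, and possibly in their controls, can differ in overlap and in gene counts for that reason alone.

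Chromosome names and lengths matched the reference used here (GRCm38, with GENCODE M21 annotation), and every peak ended within its chromosome. Location tests used chromosomes 1 to 19, X and Y, which left out 189 replicated peaks on contigs. Runs of unknown bases were removed, the chromosomes were joined end to end, and the peaks were shifted together by a random distance 10000 times, which keeps their widths and spacing. Two-sided permutation p-values count the real arrangement and were adjusted by Benjamini-Hochberg over the 23 gene lists, the features or the chromosomes. An adjusted p of 0.05 was the threshold. A gene counted as marked when at least 1 bp of its body was covered, and a promoter was taken as 1 kb on either side of a transcription start of the basic annotation. The other settings were a −log10 q of at least 5, the pooled list, each replicate list alone, other overlap rules, gene and promoter widths, cluster gaps, length-matched genes, shifts within chromosomes and leaving out Y. Clusters (at least 5 peaks at gaps of at most 50 kb) and sequence properties used 1000 draws. First and last exons were those of the transcript with the longest coding sequence. Shares have 95% Wilson intervals, which cover counting error only. With 2 replicates from separate pools of embryos, p-values describe the placement of these peaks and not the spread between animals.

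The gene lists, tests, other settings and the rule for named genes were fixed before the data were examined. The rule names the 10 genes with the most covered bases, the genes at the 10 peaks of highest fold, up to 4 marked members of each list by fold, every marked imprinted gene, and up to 3 genes of each of the 10 fullest clusters. The lists were Zfp zinc fingers, olfactory and vomeronasal receptors, clustered protocadherins, Hox, replication-dependent histones, Rhox, epidermal clusters, cytochromes P450, UDP-glucuronosyltransferases, serpins, H2 genes, ribosomal proteins, imprinted genes, germ cell genes, intestinal epithelium, gut mesenchyme, enteric neural crest, blood and endothelium, liver and pancreas, central neurons, striated muscle and H3K9 machinery.

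Some choices were made after results had been seen. The settings that use peaks found in the separate lists of both replicates and windows of 3 kb at the gene ends were added then. Alternatives were first run with 1000 shifts and then with 10000, as in the main test, which moved borderline results for UDP-glucuronosyltransferases and germ cell genes. Promoter and chromosome alternatives were followed by name for 5 lists and 4 chromosomes picked after that first run. A comparison of fold and −log10 p between the replicate lists at shared peaks was computed and then left out, because the authors' peak values were used only within a list.

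The shift test was tested on simulated peaks with 1000 shifts, fewer than the 10000 of the main test. With 1000 shifts, a list called alone had to lie beyond every shift, which keeps false calls low. The planted lists were planted together in each simulation. Without a planted signal it made 0 calls in 460 tests of the 23 lists. With a gene list hit 2 times as often as chance, it recovered 100% of 20 simulations for the Zfp list (391 genes), 50% for the imprinted list (42 genes) and 40% for the germ cell list (35 genes). At 4 times the shares were 100%, 95% and 75%. The simulated peaks were placed independently and evenly at random, without the clustering of the real peaks. These rates of false calls and recovery therefore need not hold for the real lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.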

Results

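Trimethylation of lysine 9 on histone H3 (H3K9me3), a mark of heterochromatin, was mapped by chromatin immunoprecipitation and sequencing in mouse intestine at embryonic day 14.5. There was 1 group of 2 biological replicates, with tissue pooled from 24 embryos in replicate 1 and from 34 embryos in replicate 2. No treatment, mutant or other tissue was included, so the comparisons were between the replicates and between parts of the genome. The authors' list for replicate 1 held 35752 peaks covering 10.6 Mb, and that for replicate 2 held 7098 peaks covering 1.97 Mb. A list called on both replicates together held 27814 peaks, of which the authors kept 12488 as replicated. The authors' q was 0.05 or less for 66.7% of replicate 1, 17.8% of replicate 2, 56.4% of pooled and 80.5% of replicated peaks. The lowest −log10 p of each list was between 2 and 2.09, so the lists include lenient calls, most of all in replicate 2. Read depth is unknown from these files. All coordinates are on mm10 and counted from 1, and fold enrichments are the authors' own values for each peak.

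The comparison of the replicates asked how far the 2 lists marked the same regions. On chromosomes 1 to 19, X and Y, 4443 of the 6887 replicate 2 peaks, or 64.5% (95% Wilson interval 63.4% to 65.6%), were overlapped by a replicate 1 peak. Circular shifts of the list gave 0.736% on average and 2.12% at most (permutation p = 0.0002, two-sided, the smallest that 10000 shifts can give). In the other direction 4183 of the 35499 replicate 1 peaks, or 11.8%, were overlapped, against 0.143% with shifted peaks. The Jaccard index of covered bases was 9.93%, against 0.0603% with shifted peaks. The share depended on list length. When replicate 1 was limited to its 6887 peaks with the highest −log10 p, 35% of the replicate 2 peaks were overlapped. Of the 114 replicate 2 peaks with −log10 q of at least 5, 100 had a replicate 1 peak that also met this limit. In the other direction this held for 99 of 1477 replicate 1 peaks, or 6.7%.

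The next comparison asked which pooled peaks the authors kept as replicated. Since they chose these peaks on the same samples, differences in fold are not independent evidence. Their median width was 363 bp against 224 bp, and their median fold was 3.34 against 2.8. All 12488 had the coordinates of a pooled peak. Of these, 4137 (33.1%, 95% Wilson interval 32.3% to 34%) were overlapped by peaks in the separate lists of both replicates, 6704 by replicate 1 alone, 744 by replicate 2 alone and 903 by neither. The share supported by both was 18.6% when at least 50% of a peak had to be covered, and 87.3% among replicated peaks with −log10 q of at least 5.

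Zinc finger genes carried the mark far more often than shifted peaks would give. Of 391 genes named Zfp, many of them repressors that bind DNA through arrays of zinc fingers, 145 had a replicated peak on the gene body against 36.2 expected, a ratio of 4 (adjusted permutation p = 0.0023). Zfp606 (chromosome 7, 12478293 to 12496235) had 12 peaks over 63.8% of its body, with the highest fold, 8.68, in its last coding exon, exon 7 of 7. Zfp810 on chromosome 9 reached 7.47 in its 3′ UTR, Zfp157 on chromosome 5 reached 7.32 in its last coding exon, and Zfp68 on chromosome 5 reached 7.32 with 75.7% of its body covered. Among the 145 genes, 113 were also hit in the separate lists of both replicates. The ratio was 2.27 with the replicate 1 list and 5.54 with the replicate 2 list, both past the threshold.

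Clustered protocadherins, cell adhesion proteins with most known roles in neurons, were marked on 43 of 57 genes against 11.8 expected (adjusted permutation p = 0.00307). Their gene bodies are nested, so these 43 genes rested on 104 different peaks. The 10 protein-coding genes with the most covered bases all lay in this region of chromosome 18. They were Gm42416, Gm37013 and Gm37388, long annotated genes that span the cluster, with 106629, 105024 and 104990 covered bases, and Pcdhga1, Pcdhga2, Pcdhga3, Pcdhgb1, Pcdhga4, Pcdhgb2 and Pcdhga5. Pcdhga1 (37661793 to 37841873) had 67 peaks over 41.3% of its body. Pcdhga10 was the other member named by fold, and its highest peak, shared with the genes above, was at 37752138 to 37754746 with a fold of 7.76. The result did not pass with the replicate 2 list alone (ratio 3.76, adjusted permutation p = 0.469) or with peaks of −log10 q of at least 5 (ratio 12.7, adjusted permutation p = 0.278), each of which left 2 lists past the threshold in place of 4. It did not pass with the peaks found in the separate lists of both replicates either (ratio 4.92, adjusted permutation p = 0.3).

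**Figure D1:**
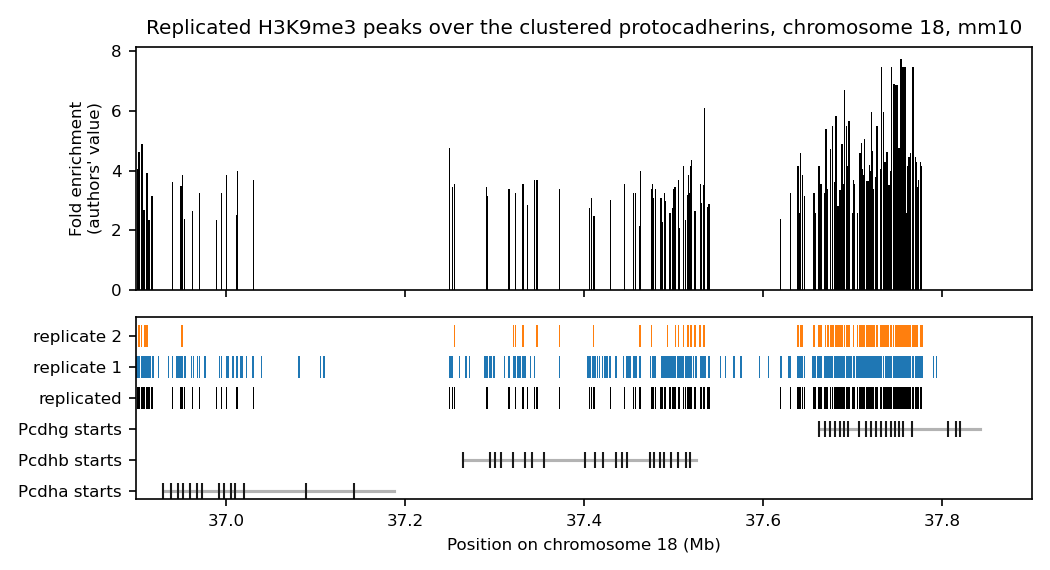
Replicated peaks over the clustered protocadherins on chromosome 18 (position in Mb, mm10), with the authors' fold enrichment of each above and the replicated list, the list of each replicate and the gene starts below. Peaks shorter than the line width are drawn wider than they are, and the fold reaches 7.76 over the gamma genes.

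Imprinted genes, which are expressed from the copy of a single parent, had the highest share of marked members. A replicated peak lay on 32 of 42 genes against 5.79 expected, a ratio of 5.53 (adjusted permutation p = 0.0023), and 30 of the 32 were hit in both separate lists. The ratio was 3.03 with the replicate 1 list, 8.93 with the replicate 2 list and 3.67 with the pooled list, all past the threshold. Grb10 (chromosome 11, 11930508 to 12038683), a growth regulator, had 10 peaks, the highest with a fold of 6.9 in intron 1. Mest on chromosome 6 reached 6.41 in intron 1, and Gnas and its antisense transcript Nespas on chromosome 2 shared a peak at 174284530 to 174287243 with a fold of 6.11. The other marked members were Gpr1 and Zdbf2 on chromosome 1, H13, Mcts2, Blcap and Nnat on chromosome 2, Sgce, Peg10, Herc3 and Nap1l5 on chromosome 6, and Peg3, Usp29, Snrpn, Mkrn3, Inpp5f, Kcnq1, Kcnq1ot1 and Cdkn1c on chromosome 7. Plagl1 on chromosome 10, Commd1 and Zrsr1 on 11, Meg3 and Rian on 12, Peg13 and Slc38a4 on 15, Igf2r and Airn on 17, and Impact on 18 completed the set. Several of these share peaks because they overlap, and the list rested on 87 different peaks.

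Olfactory receptors were marked less often, on 7 of 1093 genes against 29.5 expected, a ratio of 0.237 (adjusted permutation p = 0.00575). Olfr398, Olfr338, Olfr1490 and Olfr539 had the highest folds, from 4.19 to 3.62. This result did not pass with the pooled list (ratio 0.554, adjusted permutation p = 0.144), the replicate 1 list (0.591) or the replicate 2 list (0.576). It did not pass under 4 other settings either, which are given with the alternatives.

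Germ cell genes were marked on 10 of 35 members against 4.16 expected, which missed the threshold (adjusted permutation p = 0.0506). Ddx4 and Dazl, RNA-binding proteins of germ cells, had folds of 5.66 and 5.09, and Mael and Taf7l had 3.54 each. UDP-glucuronosyltransferases, enzymes that conjugate drugs and bilirubin, had a peak on 11 of 22 members against 3.21 expected (adjusted permutation p = 0.154). Ugt1a10, Ugt1a5, Ugt1a6a and Ugt1a6b shared the same 9 peaks on chromosome 1, with a fold of up to 3.9. Against random genes of matched length, germ cell genes passed (adjusted permutation p = 0.0445). UDP-glucuronosyltransferases also passed that test (adjusted permutation p = 0.00276), but it draws genes separately and so counts nested genes as independent, while the 11 marked genes shared 12 different peaks.

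Markers of the cells of the intestine did not differ detectably from shifted peaks. A peak lay on 1 of 33 intestinal epithelium genes (Muc13) against 2.4 expected, 2 of 24 mesenchyme genes (Pdgfrb and Ano1) against 2.06, 1 of 12 enteric neural crest genes (Gfra1) against 1.34 and 1 of 16 blood and endothelium genes (Pecam1) against 2.04. Genes of other lineages were marked on 1 of 18 members for liver and pancreas (Cyp3a11) against 0.903, 5 of 17 for central neurons, with Slc17a7, Syt1, Nrxn1 and Grin2b named, against 4.65, and 4 of 21 for striated muscle (Ttn, Ryr2, Pax3 and Ryr1) against 2.88. The vesicular glutamate transporter gene Slc17a7 had a fold of 6.71. Of the list of genes of the H3K9 methylation and silencing machinery, 2 of 26 had a peak (Morc2a and Morc3) against 3.85 expected. The adjusted permutation p was 1 for each of these 8 lists.

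No replicated peak lay on any of 39 Hox genes, 67 replication-dependent histone genes, 32 Rhox genes, 93 epidermal cluster genes or 76 ribosomal protein genes. Between 0.552 and 1.44 genes were expected in these lists, so a lower count than expected could not be shown. Vomeronasal receptors had a peak on 22 of 327 genes, with Vmn2r16, Vmn2r63, Vmn2r60 and Vmn1r59 the highest by fold. A peak lay on 2 of 72 cytochrome P450 genes (Cyp3a16 and Cyp3a11), 2 of 50 serpins (Serpina9 and Serpinb6d) and 2 of 34 H2 genes (H2-T24 and H2-Ob). None of these lists passed the test, with adjusted permutation p from 0.57 to 1.

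**Figure D2:**
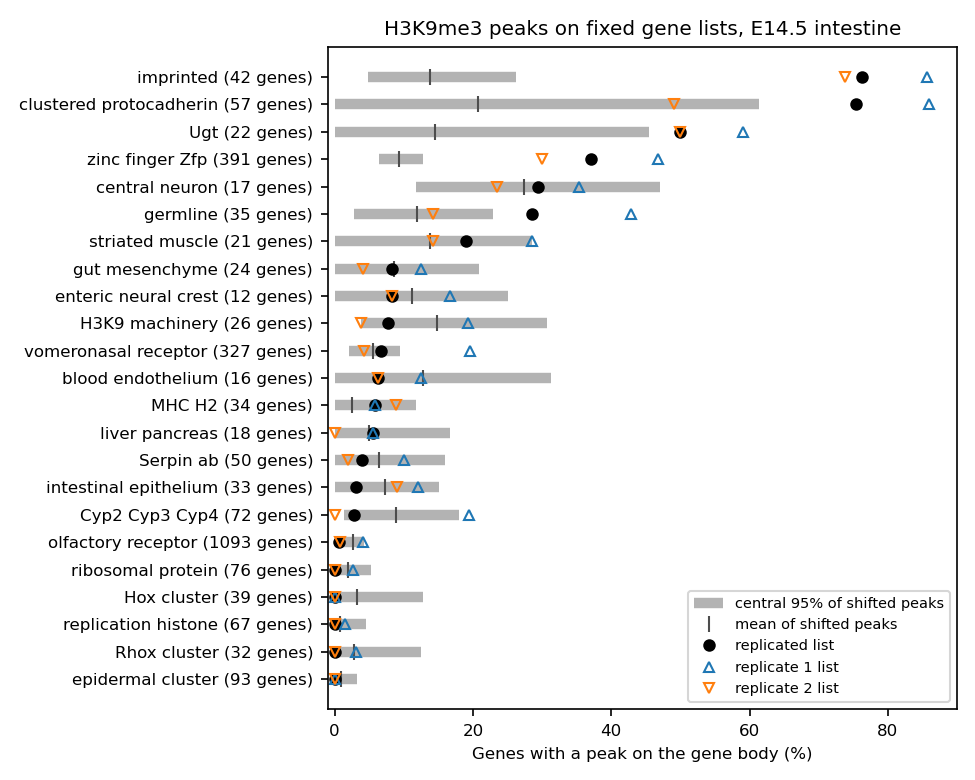
Share of the genes of each fixed list with a peak on the gene body (%), for the replicated list and for the list of each replicate. Grey bars and ticks give the central 95% and the mean of 10000 shifts of the replicated peaks, and imprinted genes (76.2%) and clustered protocadherins (75.4%) have the highest shares in the replicated list.

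Promoters of germ cell genes stood out more clearly than their gene bodies. Within 1 kb of a transcription start, 8 of 35 germ cell genes had a replicated peak against 0.372 expected (adjusted permutation p = 0.00115). These were Mael, Sohlh2, Brdt, Fkbp6, Ddx4, Smc1b, Dazl and Taf7l, and 4 of them, Fkbp6, Ddx4, Smc1b and Dazl, were hit in the lists of both replicates. Sohlh2, Brdt, Fkbp6 and Smc1b are outside the rule for named genes and were chosen after their values were seen. Promoters were also marked for 30 of 57 protocadherins against 0.574 expected, 24 of 42 imprinted genes against 0.712, and 24 of 391 Zfp genes against 5.32, each with an adjusted permutation p of 0.00115. These 4 lists passed under every setting run, but their ratios depended on the peak list. From the pooled list to peaks with −log10 q of at least 5, the ratio went from 2.77 to 21.4 for Zfp genes, 18.8 to 172 for imprinted genes, 11.8 to 53.9 for germ cell genes and 35.2 to 250 for protocadherins. Olfactory receptors had 3 of 1093 promoters marked against 18.9 expected (adjusted permutation p = 0.00276), and of the other settings only the pooled list passed. No promoter of the intestinal epithelium, mesenchyme, enteric neural crest or endothelium lists was marked. These lists hold 12 to 33 genes, and the 35 germ cell genes had 0.372 expected, so a lower count than expected could not be shown.

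Zfp genes had a peak on the last exon, where most of the zinc finger array is usually encoded, more often than on the first. Of 388 Zfp genes with more than 1 exon, 105 had a replicated peak on the last exon but not the first, 1 had the reverse and 2 had both (exact sign test p = 2.64e-30, two-sided). Not all peaks lay there, and in 45 of the 145 marked Zfp genes the summit with the highest fold was in an intron. Among 20030 other protein-coding genes the numbers were 170 and 83. Last exons of Zfp genes are long, and among the 90 genes whose last exon was at most 2 times as long as the other exons together, 10 had a peak on the last exon only and 1 on the first only (exact sign test p = 0.0117). Genes are not independent replicates, and many Zfp genes lie next to each other.

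Exons held 10.8% of replicated peak bases against 3.97% for shifted peaks, and promoters held 7.04% against 4.37%, each with an adjusted permutation p of 0.0008. Pseudogenes (1.85% against 1.12%, adjusted permutation p = 0.0123) and long noncoding RNA genes (9.58% against 7.18%, adjusted permutation p = 0.004) were also over-represented. Protein-coding gene bodies held 45.7% against 39.2%, and intergenic sequence held 46.1% against 54%, each with an adjusted permutation p of 0.004. The result for pseudogenes did not pass with peaks of −log10 q of at least 5 (adjusted permutation p = 0.0512), and that for protein-coding gene bodies did not pass with the replicate 1 list (adjusted permutation p = 0.262). Introns held 43.1% against 42.1% (adjusted permutation p = 0.526). Peak sequence had a GC content of 45.6% against 41.7%, a CpG observed/expected ratio of 0.218 against 0.19 and 26.2% soft-masked repeat bases against 36.4% (permutation p = 0.002 each, the smallest that 1000 shifts can give). The CpG ratio within 200 bp around the summit, 0.195, did not pass (adjusted permutation p = 0.106). Shifts left out only runs of unknown bases, so shifted peaks could land in repeats where reads cannot be placed uniquely. Whether the lower repeat share and the other differences reflect this or the mark was not tested.

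The X and Y chromosomes held few peaks. Replicated peaks numbered 0.587 per Mb of gap-free sequence on X and 0.034 on Y, while the autosomes ranged from 3.46 on chromosome 3 to 7.51 on chromosome 17. Chromosome 7 held the most peaks, 1041. X was also below every autosome in the list of each replicate, with 2.32 per Mb in replicate 1 and 0.483 in replicate 2. Because a circular shift moves long stretches of peaks together, this test has little power for whole chromosomes. Only Y, with 3 peaks, passed it (adjusted permutation p = 0.0378), and X did not (adjusted permutation p = 0.619). Y did not pass with peaks of −log10 q of at least 5 (adjusted permutation p = 0.832) or with the peaks found in both separate lists (adjusted permutation p = 0.0546). The shifts treated all 88.1 Mb of gap-free Y sequence as able to hold peaks, also repeats where reads cannot be placed uniquely. Whether the few peaks on Y reflect read placement, copy number in pools of both sexes or the mark was not tested.

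**Figure D3:**
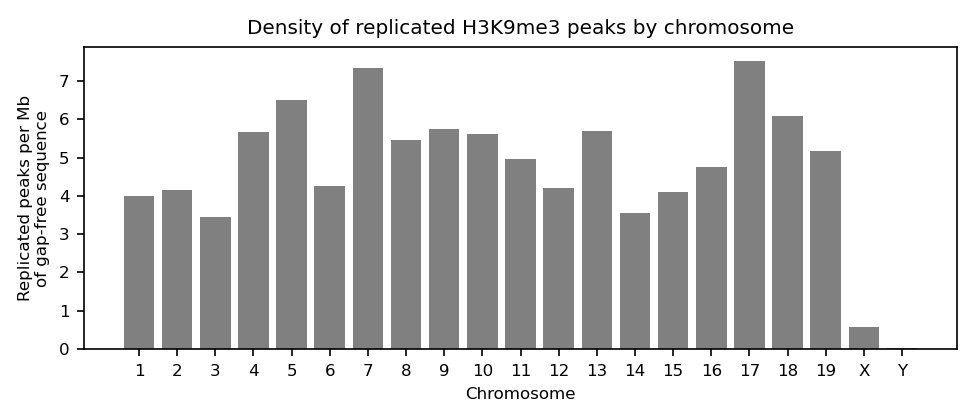
Replicated peaks per Mb of gap-free sequence (vertical axis) on each chromosome (horizontal axis). Chromosome X stands at 0.587 and Y at 0.034, below every autosome.

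Peaks were clustered. At gaps of at most 50 kb, 310 clusters held at least 5 replicated peaks each, against 33.4 on average and 53 at most when peaks were placed at random on their own chromosomes (permutation p = 0.002, the smallest that 1000 draws can give). The excess over random placement depended on the list, with 144 clusters against 3.03 expected for replicate 2 and 1728 against 1316 expected for replicate 1. The 310 clusters held 24% of the peaks on chromosomes, and 46 of them included a marked Zfp gene. The fullest cluster, on chromosome 18 at 37618469 to 37775651, held 77 peaks over the gamma protocadherins. Genes of a cluster were ordered by covered bases over their whole bodies, which can reach outside the cluster. By that order Gm42416, Gm37013 and Gm37388 led here, and also in a further cluster of 52 peaks on chromosome 18 at 37248910 to 37538903. On chromosome 4, 147335055 to 147613257, 53 peaks included Zfp982 and Zfp979, which had 1551 and 332 covered bases against 21127 peak bases in the cluster. On chromosome 1, 88171001 to 88310841, 52 peaks lay at Mroh2a and Trpm8, a cold-sensing channel, and reached Ugt1a7c. Replicated peaks covered 72.3% of the whole body of Mroh2a and 14.5% of that of Trpm8. On chromosome 7, 33619442 to 33943007, 51 peaks included the secretoglobins Scgb2b24, Scgb1b24 and Scgb2b26. These genes had 1690, 295 and 6 covered bases, against 23248 peak bases in the cluster, so most of it lay outside them. The remaining leading clusters lay at Zfp873, AU041133 and Zfp938 on chromosome 10 (48 peaks), D130040H23Rik on chromosome 8 (35), Zfp369 and Gm10775 on chromosome 13 (34), Zfp850, Zfp60 and Zfp607b on chromosome 7 (34), and Zfp981 and Zfp992 on chromosome 4 (33).

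The 10 replicated peaks with the highest fold were all present in the lists of both replicates. The highest, with a fold of 12.9, lay on chromosome 13 at 119488027 to 119489231 over 3110070M22Rik and Tmem267, 6274 bp from an assembly gap. The second, with a fold of 11.5, and the sixth, with 8.23, lay on contigs without a known position on a chromosome, the second over CAAA01118383.1. On X, a peak over Gm21887 (170008974 to 170010037) had a fold of 10.1, and 2 peaks over Asmt, a melatonin synthesis gene, had 8.68 and 8.04, the former 29 bp from a gap. The others were Zfp606 on chromosome 7, Il3ra with the antisense gene Gm48860 on chromosome 14 (8.08), coding exon 10 of the mitochondrial RNA polymerase gene Polrmt on chromosome 10 (7.93), and Gm26573 with Gm13245 on chromosome 4 (7.89).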

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

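In this part, the floors on the X chromosome above the lowest values of the list were chosen only after the result was seen. The location tests left out 189 replicated peaks on 17 contigs without a known position on a chromosome, which is data outside the main comparisons. They made up 1.51% of the 12488 replicated peaks, but 100 of the 1209 with −log10 q of at least 5 (8.27%). Contig genes with a peak included CAAA01118383.1 with 3, which the rule names, and AC149090.1 with 4, named after its value was seen.

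The strong peaks on chromosomes also gathered beside assembly gaps. Of 1109 peaks with −log10 q of at least 5, 7.57% lay within 50 kb of a gap against 0.971% of shifted peaks, a ratio of 7.8 (permutation p = 0.0002, the smallest these shifts can give). For the other replicated peaks the ratio was 2.36. This met the criterion written beforehand for sequence with more copies in the mice than in the assembly. More of the mark beside gaps would give the same result, so nearness to a gap cannot tell these apart. Fold was read as a ratio to control, which extra copies could raise too. Whether some of the strongest peaks reflect collapsed copies and not only more H3K9me3 per copy stays open. Copy number was not measured here, and no biological explanation was tested.

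Chromosome X held 0.587 replicated peaks per Mb against 5.09 on the autosomes. GC content and the share of soft-masked bases did not account for this. X had 0.146 of the density of autosomal 100 kb windows matched on both (95% block bootstrap interval 0.0749 to 0.249). The matching did not consider where reads can be placed uniquely, so a part played by repeats in which they cannot stays open. Fewer copies of X in male embryos could lower −log10 p. Fold was read as a ratio to control, which could fall with the same copies, and fold then need not change. However, peaks on different chromosomes, at Zfp606 and Asmt, had the same fold (8.68) and −log10 p (28.1). How the control entered these values is unknown, so whether fold would change cannot be told. The test halved both values, and the pools held both sexes, so halving is harsher than the pools would need. Against autosomal peaks that stayed above the lowest fold and −log10 p of the list after halving, X had 0.137 of the density (0.0701 to 0.238), which met the criterion written beforehand for excluding this explanation. That criterion rested on the extreme minimum of the list. With a floor at the 5th percentile, 96.2% of autosomal peaks were lost and the ratio became 2.72. Folds lay close together (quartiles 2.97 to 3.77), so halving them against a floor of the unhalved list removes nearly all peaks. The test therefore cannot decide between copy number and a lower level of the mark on X. No biological explanation was tested, since the design has no group by sex.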

How the results depend on the processing

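The peaks found in both separate lists and the 3 kb windows were chosen only after the data were seen. Of 384 comparisons with an alternative, 319 were classed as unchanged. For a single test this means that its direction and its side of the threshold were kept. Lists without a marked gene under both settings were classed this way too. Counts of tests past the threshold had only to stay of similar size, clusters also on the same side of the threshold. The share supported by both replicates had to stay within its Wilson interval. The Zfp and imprinted lists passed under every alternative run, with ratios of 2.27 to 17.6 and 3.03 to 32.6. Where results changed, the cause was not tested. Ratios of observed to expected genes follow unless stated.

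With −log10 q of at least 5, olfactory receptors (0), protocadherins (12.7) and pseudogene bodies (2.26) no longer passed, 2 lists and 0 chromosomes passed, 28 clusters remained, and the share of replicated peaks supported by both replicates was 87.3%. The direction turned for vomeronasal receptors, H2 genes, liver and pancreas and striated muscle (0 each) and for enteric neural crest (6.46). With at least 50% of a peak covered, the supported share was 18.6%.

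With the pooled list, olfactory receptors (0.554) no longer passed, the direction turned for intestinal epithelium (1.15), liver and pancreas (0.563) and introns (0.996), and there were 1203 clusters.

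With a single replicate list, ratios ranged from 0.576 to 0.591 for olfactory receptors, 2.23 to 3.76 for protocadherins, 0.745 to 2.15 for intestinal epithelium, 0.731 to 1.23 for enteric neural crest, 0 to 0.445 for liver and pancreas, 0.931 to 6.67 for H2 genes, 0.833 to 1.16 for central neurons, 1.04 to 1.25 for protein-coding gene bodies and 0.985 to 1.01 for introns. Between 2 and 3 lists passed, and clusters numbered 144 to 1728.

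With peaks found in both separate lists, olfactory receptors (0.195) and protocadherins (4.92) no longer passed, UDP-glucuronosyltransferases (8.74) did, 0 chromosomes passed and there were 68 clusters. The direction turned for vomeronasal receptors (0.466), intestinal epithelium (1.1), mesenchyme (1.29), enteric neural crest (1.84), blood and endothelium (1.28) and liver and pancreas (0).

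With at least 1 kb covered, or 10% of genes shorter than 10 kb, olfactory receptors (0) no longer passed and UDP-glucuronosyltransferases (16.4) did, and the direction turned for vomeronasal receptors (0.412), H2 genes (0), enteric neural crest (3.5) and liver and pancreas (0). With 5 kb on either side, olfactory receptors (0.63) no longer passed, and the direction turned for cytochromes P450 (1.29) and enteric neural crest (1.78). Against genes matched on length, UDP-glucuronosyltransferases (2.96) and germ cell genes (2.19) passed, but that test counts the nested UDP-glucuronosyltransferase genes as independent. Without Y, introns turned (0.996).

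Gaps of 20 kb and 100 kb gave 185 and 510 clusters. For promoters of olfactory receptors, the result did not pass with −log10 q of at least 5 (0), a single replicate list (0.313 to 0.534), peaks found in both separate lists (0.3) or 5 kb on either side of the start (0.552). With those 5 kb, promoter ratios were 3.54 for Zfp genes, 19.7 for protocadherins, 12.5 for imprinted genes and 5.74 for germ cell genes. The CpG ratio within 200 bp of the summit (0.195) did not pass. Among the promoter and chromosome results not followed by name, 13 of 108 and 5 of 85 turned, 0 of them with a call. Most lists whose direction turned have few marked genes. Read depth is unknown, so what depth limits could not be measured. No paired analysis was possible because there was 1 group.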

Other observations

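The coverage of parts of the last exon, the scan of symbol groups and the distance of imprinted genes were tests chosen only after results were seen. Zinc finger genes outside the Zfp list also carried the mark at the last exon. Among 175 such genes with at least 5 C2H2 motifs, 24 (13.7%, 95% Wilson interval 9.39% to 19.6%) had a replicated peak there against 2.25 expected, a ratio of 10.6 (permutation p = 0.0002, the smallest these shifts can give). They included 2610008E11Rik on chromosome 10 with a fold of 7.17 and Repin1 on chromosome 6 with 6.76, both named after their values were seen. Genes without a motif had 159 of 19678 last exons marked, 0.961 times the expected number. Of Zfp genes with at least 5 motifs, 104 of 312 were marked, against 3 of 76 with fewer motifs (permutation p = 0.121 for the latter).

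A candidate explanation is that peaks follow the zinc finger array whatever the gene is called. The genes outside the Zfp list were set apart by symbol alone. Among those marked, AU041133 lay in the same cluster of peaks as Zfp873 and Zfp938. AI987944, AW146154 and Gm6871 lay close together on chromosome 7. The comparison therefore cannot separate the array from shared gene family or neighbouring position. Long last exons alone did not account for the pattern, since genes without a motif matched on last exon length were marked 0.0418 times as often as Zfp genes (95% bootstrap interval 0.0325 to 0.0546). Within the last exons of 103 Zfp genes with at least 5 motifs and a peak there, peaks covered 65.4% of array bases. They covered 59% of other coding bases and 29.4% of 3′ UTR bases. The array was covered more than the 3′ UTR in 72 genes and less in 20 (exact sign test p = 4.61e-08). Array and other coding bases were not compared by a test. The result therefore sets the array apart from the 3′ UTR but not from the rest of the coding sequence. Reads shared between similar arrays were not tested and stay open, as the deposited peaks hold no reads.

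The 10 imprinted genes without a peak on the gene body were Dlk1, H19, Igf2, Magel2, Ndn, Peg12, Phlda2, Rasgrf1, Rtl1 and Zim1. Their median distance to the nearest replicated peak was 24.2 kb, against a median of 135 kb over the shifts (permutation p = 0.018). The distribution of the shifts is skewed, with a mean of 248 kb. The nearest peak lay 0.033 kb from Magel2, 1.67 kb from H19, 2.34 kb from Igf2 and 62.4 kb from Dlk1. For 3 of the 10, Peg12, Rtl1 and Zim1, that peak lay on another imprinted gene already counted as marked. The test shows only nearness to a peak, in the genes in which it was noticed.

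Groups of protein-coding genes that share the letters at the start of their symbol were also scanned, leaving out groups in which at least 50% of genes were on a fixed list, such as Zfp. Some of these groups are not gene families. The 261 groups of at least 10 members gave 0 calls at an adjusted permutation p under 0.05 and 8 at an unadjusted p under 0.05. The leading group was Zkscan, zinc finger genes with a SCAN domain, with 4 of 11 genes marked against 0.716 expected (permutation p = 0.0088, adjusted p = 1).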
